A study of Mus musculus with 24 samples.

How the data were processed

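The series holds 24 Affymetrix GeneChip arrays of mouse eWAT, 1 per mouse, in 8 groups of 3 by genotype (CON, MUT) and circadian time (CT1, 7, 13, 19). Total RNA was isolated with Trizol and labelled with biotin by the authors. The deposited values are log2 expression values per probe set that the authors made with RMA and Affymetrix Expression Console. The versions and settings of these tools, and the genome build behind the probe annotation, are not given in the sources used here. The values run from 4.157 to 14.5, with array medians from 7.802 to 7.936 and correlations between arrays from 0.9569 to 0.9922. Precision is set by the 3 arrays per group and by signal over background. The source field of the labels names mediobasal hypothalamus, while titles and treatment text name eWAT, so marker genes of both tissues were looked up in the signals.

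Of the probe sets, 23521 carry 1 gene symbol, 1814 several and 9055 none. Symbols were matched by Entrez identifier to the GRCm38.p6 annotation for names and gene order only, and 193 of the single symbols found no match. The brightest probe set of each of 22180 genes was taken, and genes under the 30th percentile of mean signal (7.416) were left out, which leaves 15526. Probe sets with several symbols, Per2 among them, were not used in the comparisons and no gene sharing a probe set is named.

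A cell-means model with 16 residual degrees of freedom was fitted to all arrays with limma 3.58.1 in R 4.3.3. Rhythms were tested with 24-h cosine and sine contrasts (moderated F, 2 df) in CON, in MUT and for their difference, whose size is the peak-to-trough of the vector difference. MUT was compared with CON in the daily mean and at each time point with limma's moderated test, two-sided. P-values were adjusted by the Benjamini-Hochberg method over all genes, and 0.05 was the threshold. Gene lists were tested with Fisher's exact test, one-sided, for rhythms and with camera for genotype differences, at a preset correlation of 0.01 and with an estimated correlation, adjusted over 32 lists. The ratio of summed squared amplitudes was tested over all genes and over the clock lists by exact permutation of genotype within time points (160000 assignments, two-sided). The spread between mice and the agreement of single-array clock times were tested by permutation, two-sided. The comparisons, lists, naming rule and most alternatives were fixed before the data were examined. The common phase shift, the tests per list of shift and ratio, and the alternatives with the level trend removed, the mesothelium score as a covariate and 3 arrays of narrow spread left out were chosen after seeing the data. So were the list tests after quantile normalization and without each array, and the test of the synthesis list's rhythm in CON by exact permutation of the CON arrays over time points. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

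The text names the members of the 3 clock lists. Among genes past the threshold it names the 12 largest rhythms or vector differences, or the 8 highest and 8 lowest differences, and up to 4 members per other list and comparison with the smallest p. Arntl and Syt10 are given in every group. The lists were clock activators, repressors and outputs, fatty acid and triglyceride synthesis, lipolysis and fatty acid handling, fatty acid oxidation, insulin signalling and glucose use, adipokines, cholesterol synthesis, heat shock proteins, cold-inducible RNA-binding proteins, unfolded protein response, glucocorticoid targets, immediate early genes, interferon response, inflammation, extracellular matrix, oxidative phosphorylation and cell cycle. Marker lists covered adipocytes, hypothalamus and neurons, epididymis, macrophages, T cells, B cells, endothelium, fibroblasts and preadipocytes, mesothelium, smooth muscle and pericytes, skeletal muscle, erythrocytes and brown adipocytes. Members without a tested probe set of their own include Per2, Lonrf3, Por, Scd2, Adrb3, Cpt1b, Ucp2, Cfd, Idi1, Rbm3, Il1b and Il6.

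The models were tested on simulated data in which 200 of 15526 genes were changed. At 1.5-fold the recovered share was 92% for rhythms in CON, 98% in MUT, 54% for differential rhythm, 100% for the daily mean and 92 to 96% at single time points. At 1.2-fold it was 26%, 22%, 4%, 86% and 30 to 38%, and false calls numbered 3 to 16. The simulated noise was independent between genes, so these numbers do not cover false calls from structure that genes of real arrays share. The alternatives were quantile normalization, arrays shifted to the same median, each array left out, the letters of the titles as a block, no level filter, a filter at the 60th percentile, the mean of a gene's probe sets and all probe sets. Others were array weights, trended and robust variance, a fold of at least 1.5, an F test over 4 time points without a cosine, fits of the arrays of a genotype or time point alone, and clock lists without outputs.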

Results

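Gene expression was measured in epididymal white adipose tissue (eWAT), the fat pad beside the mouse testis, with 24 Affymetrix GeneChip arrays, 1 per mouse. MUT mice (Syt10-Cre/Cre x Bmal1 flox/-) lack circadian clock function in the suprachiasmatic nucleus (SCN), the pacemaker in the hypothalamus. CON mice (Syt10-Cre/Cre x Bmal1 +/-) were the controls. After 2 weeks in a light-dark cycle the mice were released into constant darkness, and tissue was taken on the second day at circadian time (CT) 1, 7, 13 and 19. Each of the 8 groups of genotype and time held 3 arrays. Every array gave a log2 signal per probe set, with array medians between 7.802 and 7.936. The comparisons covered 15526 genes with 1 probe set each. The series asks which daily rhythms of the transcriptome remain without a working SCN clock. For rhythms, the size is the log2 peak-to-trough of a fitted 24-h cosine, and errors are SE of the limma model over 3 arrays per group unless said otherwise. The number of arrays limits the precision of every value.

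The labels disagree on the tissue: the titles and the treatment text name eWAT, and the source field names mediobasal hypothalamus. The 10 measured adipocyte markers lay at a median percentile of 99.6 of the signal of all genes, with a median log2 signal of 12.5. The 13 hypothalamus and neuron markers lay at a median percentile of 44.9. Markers of endothelium (91.5), of fibroblasts and preadipocytes (89.1), of smooth muscle and pericytes (84), of macrophages (81.5) and of mesothelium (67.3) lay between these. Erythrocyte (60, 1 marker), B cell (42.8), skeletal muscle (42.5), brown adipocyte (41.6), T cell (28) and epididymis (22.9) markers were the remaining lists. Arntl, which encodes BMAL1 and is the floxed gene, was at 8.95 ± 0.20 (SD, n = 3) in CON at CT1, 8.07 ± 0.09 at CT7, 8.36 ± 0.29 at CT13 and 9.54 ± 0.09 at CT19. In MUT Arntl was at 8.49 ± 0.27, 8.19 ± 0.24, 9.52 ± 0.06 and 9.15 ± 0.21 at the same times, and its daily mean differed by 0.11 (adjusted p = 0.277). Syt10, whose promoter drives Cre, was at 7.52 ± 0.05, 7.51 ± 0.12, 7.59 ± 0.08 and 7.62 ± 0.08 in CON and at 7.42 ± 0.06, 7.49 ± 0.13, 7.39 ± 0.14 and 7.33 ± 0.09 in MUT. Its daily mean fell by 0.15 in MUT (adjusted p = 0.0141). These signals lie near the level filter of 7.416, and in the dimmest of 10 equal bins of genes 260 were called lower in MUT and 35 higher.

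In CON, 2650 of 15526 genes (17.1%) had a 24-h rhythm at a Benjamini-Hochberg adjusted p under 0.05, and 17 of the 20 measured clock genes were among them. Nr1d1, which encodes the nuclear receptor REV-ERB alpha and represses Arntl, had the largest rhythm of all, 3.44 ± 0.17 (10.8-fold) with its peak at CT4.65. The transcription factor gene Dbp followed among the clock genes at 2.21 ± 0.17 (4.63-fold, CT8.05), then Nr1d2 at 2.06 ± 0.19 (CT6.88). Genes of the activating limb peaked late in the subjective night: Arntl at CT20.5 (1.59 ± 0.15), Clock at CT20.8 (0.89 ± 0.09) and Npas2, whose protein partners BMAL1, at CT21.6 (1.87 ± 0.17). Per1 (1.31 ± 0.14, CT8.34), Per3 (1.79 ± 0.16, CT8.89), Ciart (1.07 ± 0.07, CT7.6) and Tef (1.04 ± 0.11, CT9.21) peaked in the late subjective day. Usp2 (CT12.3), Wee1 (CT12.6), Tspan4 (CT12.1) and Hlf (CT10.6) followed, and Bhlhe40 (1.66 ± 0.22, CT16), Cry1 (0.52 ± 0.09, CT16.4) and Nfil3 (0.97 ± 0.10, CT17.5) peaked in the subjective night. The fixed lists gave 7 of 7 clock outputs (adjusted p = 0.000134, Fisher's exact test, one-sided), 7 of 9 repressors (adjusted p = 0.000875) and 3 of 4 activators (adjusted p = 0.0504). The counts adjusted over the list alone were also 7, 7 and 3. Rora, Cry2 and Bhlhe41 did not pass, with fitted sizes of 0.08, 0.07 and 0.39. Bhlhe41 was not flat: its means were 7.949, 9.17, 8.336 and 9.15 at CT1, 7, 13 and 19, an alternation that a 24-h cosine does not measure.

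**Figure D1:**
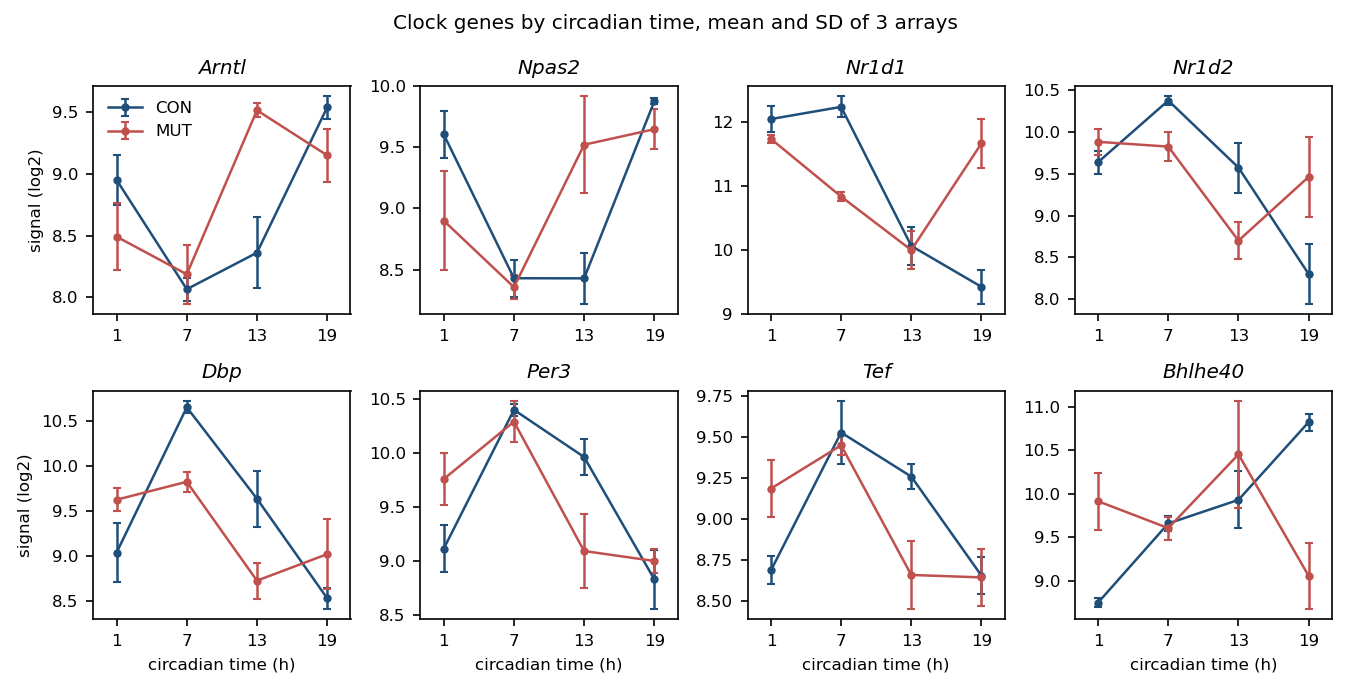
Log2 signal of 8 clock genes against circadian time in hours, as the mean and SD of 3 arrays, with CON in blue and MUT in red. Arntl in CON had its highest mean at CT19 (9.54) and in MUT at CT13 (9.52). Each panel has its own vertical axis.

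Angptl8, whose protein regulates lipoprotein lipase, cycled by 2.79 ± 0.33 (6.9-fold) with its peak at CT17.8. Asb12 (2.02 ± 0.21, CT19.5), Pnpla3, which encodes a lipid droplet hydrolase (1.63 ± 0.19, CT19.1), Cdkn1a, which encodes a cell cycle inhibitor (1.70 ± 0.16, CT19.7), Gpm6a (1.63 ± 0.35, CT17.7) and Serpina3b (1.71 ± 0.33, CT4.79) completed the 12 largest rhythms. Of the list for insulin signalling and glucose use, 8 of 14 members passed (9 adjusted over the list alone, adjusted p = 0.00368). Ppp1r3c and Ppp1r3b, which encode subunits that target a phosphatase to glycogen, peaked at CT17.2 with sizes of 1.36 ± 0.18 and 1.31 ± 0.25. Pfkfb3, a regulator of glycolysis (0.89 ± 0.10, CT2.89), and Insr, the insulin receptor gene (0.45 ± 0.08, CT4.31), peaked early in the subjective day. Of the adipokines 5 of 8 passed (5 adjusted over the list alone, adjusted p = 0.0182), among them Lep, which encodes leptin (1.38 ± 0.14, CT16.5), Nampt (0.55 ± 0.11, CT15.8), Nrg4 (0.53 ± 0.09, CT10.5) and Agt (0.45 ± 0.11, CT2.5), whose call ended without any 1 of 3 arrays. The call of the adipokine list ended with the trend on signal level removed.

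Of the cholesterol synthesis genes 9 of 12 were rhythmic in CON (11 adjusted over the list alone, adjusted p = 0.00026), with a circular mean peak at CT20.5. Hmgcs1 (0.96 ± 0.14), Sqle (0.84 ± 0.14), Sc5d (0.77 ± 0.12) and Srebf2, which encodes the transcription factor of the pathway (0.39 ± 0.06), were members. Of the lipolysis and fatty acid handling list 6 of 13 passed (7 adjusted over the list alone, adjusted p = 0.0454). Angptl4, whose protein inhibits lipoprotein lipase, peaked at CT3.53 (0.93 ± 0.13), Mgll at CT3.2 (0.38 ± 0.08) and Gpihbp1, which anchors that lipase on capillaries, at CT6.63 (0.50 ± 0.09). G0s2, whose protein inhibits the first step of lipolysis, peaked at CT17.6 (0.80 ± 0.17). Of fatty acid and triglyceride synthesis 1 of 17 members passed, Elovl6 (1.42 ± 0.33, CT20.2), whose call ended without either of 2 arrays. Of fatty acid oxidation 5 of 13 passed (6 adjusted over the list alone, adjusted p = 0.137), with a circular mean peak at CT3.74 and Acadl (0.54 ± 0.09) and Ppara (0.45 ± 0.11, not called without either of 2 arrays) as examples.

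Of the heat shock protein genes 7 of 11 were rhythmic in CON (8 adjusted over the list alone, adjusted p = 0.00368), with a circular mean peak at CT17.2. Hsph1 cycled by 0.78 ± 0.16, Hspa8 by 0.65 ± 0.07, Hspa1b by 0.65 ± 0.13 and Serpinh1 by 0.58 ± 0.12. Cirbp, a cold-inducible RNA-binding protein gene, peaked at CT2.57 (0.51 ± 0.11) and was 1 of 2 measured members of its list. Of the glucocorticoid targets 4 of 12 passed (7 adjusted over the list alone, adjusted p = 0.285), among them Tsc22d3 (0.84 ± 0.08, CT14), Fkbp5 (0.54 ± 0.12, CT13.1) and Sgk1 (0.55 ± 0.15, CT8.01). The calls of Fkbp5 and Sgk1 ended without any 1 of 2 and 4 arrays. Of the extracellular matrix genes 8 of 13 passed (10 adjusted over the list alone, adjusted p = 0.0026), with Fn1 at 0.97 ± 0.15 (CT16.8), Lox, which encodes a collagen cross-linking enzyme, at 0.60 ± 0.10 (CT19.8), Col4a2 at 0.49 ± 0.10 and Col5a1 at 0.42 ± 0.08. This list call ended after quantile normalization and with the trend on signal level removed. The remaining lists did not pass as lists. Their counts were 4 of 16 for oxidative phosphorylation, 2 of 13 for the unfolded protein response, 2 of 11 for immediate early genes, 1 of 9 for interferon response, 1 of 10 for inflammation and 0 of 9 for cell cycle.

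Markers of some other cell types were rhythmic in CON. Of the mesothelium list 7 of 8 passed (adjusted p = 0.000304), with a circular mean peak at CT17.6, and Muc16 (1.38 ± 0.32), Upk3b (1.17 ± 0.25), Krt8 (1.01 ± 0.17) and Krt19 (0.80 ± 0.18) were its members with the smallest p. The mesothelium score, the median deviation of the list per array, was -0.65 ± 0.04 (SD, n = 3) in CON at CT7, -0.24 ± 0.24 at CT1, 0.10 ± 0.30 at CT13 and 0.25 ± 0.12 at CT19. Of the fibroblast and preadipocyte list 5 of 8 passed (7 adjusted over the list alone, adjusted p = 0.0182), with Dpp4 at 1.14 ± 0.26, Pi16 at 1.05 ± 0.20, Cd34 at 0.63 ± 0.10 and Dcn at 0.44 ± 0.10, and a circular mean peak at CT18.4. The call of this list also ended after quantile normalization and with the trend on signal level removed. Of the macrophage list 4 of 11 passed and of the endothelium list 4 of 8, with circular mean peaks at CT17.9 and CT3.26, and neither list passed (adjusted p = 0.234 and adjusted p = 0.0885). The counts were 2 of 10 for adipocytes (Lep, and Lipe, whose call ended without any 1 of 5 arrays), 1 of 7 for smooth muscle and pericytes, 1 of 10 for hypothalamus and neurons and 1 of 6 for brown adipocytes. They were 0 of 3 for T cells, 0 of 5 for B cells, 0 of 5 for epididymis, 0 of 4 for skeletal muscle and 0 of 1 for erythrocytes. The CON calls of Gpm6a, Serpina3b, Insr, Mgll, Hsph1, Serpinh1, Fn1, Dpp4, Pi16, Cd34 and Dcn ended under 1 alternative other than an omitted array. Each called clock gene kept its CON call under every alternative run for single genes. With the mesothelium score as a covariate 51 of 85 named gene calls in CON held. The count of rhythmic genes in CON was then 1470, 1200 of them among the 2650. Without 3 arrays of narrow signal spread (CON CT7 replicates 2 and 3 and CON CT13 replicate 1) the count was 1011, and 8 other omissions of as many arrays of these groups gave 651 to 1529.

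Of the 2650 genes, 38.5% peaked from CT0 to CT6, 6.6% from CT6 to CT12, 22.2% from CT12 to CT18 and 32.8% from CT18 to CT24. Their median size was 0.38, and 431 of them reached 1.5-fold. Sampling every 6 h gave 4 points per cycle, so that the peak times rest on the shape of the fitted cosine.

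In MUT, 54 genes had a 24-h rhythm at the same threshold, and 12 of the 20 clock genes were among them. Nr1d1 again had the largest rhythm, 1.93 ± 0.17 (3.8-fold, CT23.3). Per3 (1.46 ± 0.16, CT5.18), Npas2 (1.44 ± 0.17, CT17.3), Arntl (1.41 ± 0.15, CT15.9), Nr1d2 (1.23 ± 0.19, CT2.14), Dbp (1.21 ± 0.17, CT3.79) and Tef (0.96 ± 0.11, CT4.79) were also among the 12 largest. Per1, Usp2, Wee1, Nfil3 and Clock passed with sizes of 0.89, 0.87, 0.86, 0.63 and 0.52. Outside the clock lists, Aacs, which encodes acetoacetyl-CoA synthetase, cycled by 1.14 ± 0.20 (CT8.24). Pdk4, an inhibitor of pyruvate dehydrogenase, cycled by 1.03 ± 0.14 (CT19.8), Alox15 by 0.89 ± 0.14 (CT16.6), and Lyz1 and Zbtb16 by 1.03 ± 0.20 and 0.90 ± 0.18, with adjusted p of 0.0478 and 0.0492. Lyz1 and Zbtb16 did not pass without any 1 of 16 and 19 arrays, and Aacs without any 1 of 4. The calls of Angptl4 (7 arrays), Nampt (5), Cdkn1a (4), Clock (2), Nrg4 (2) and Nfil3 (1) in MUT also ended without single arrays. Fisher's exact test, one-sided, gave an adjusted p of 2.81e-10 for 5 of 7 clock outputs, 2.6e-07 for 4 of 9 repressors and 1.69e-06 for 3 of 4 activators. Adjusted over the list alone, 6, 8 and 3 members passed. Of the glucocorticoid targets 3 of 12 passed (6 adjusted over the list alone, adjusted p = 6.85e-05), namely Pdk4, Zbtb16 and Cdkn1a (0.88 ± 0.16). This list call ended after quantile normalization. Of the adipokines 2 of 8 passed (2 adjusted over the list alone, adjusted p = 0.0021), namely Nrg4 (0.59 ± 0.09, CT6.64) and Nampt (0.60 ± 0.11, CT8.12).

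Angptl4, of the lipolysis list, also passed in MUT (0.72 ± 0.13, CT19.8). For mesothelium, 0 of 8 members passed over all genes and 7 adjusted over the list alone, with a median fitted size of 0.72. The counts over all genes were 0 for heat shock, cholesterol synthesis, extracellular matrix and insulin signalling, and 2, 1, 5 and 3 adjusted over these lists alone. At an unadjusted p under 0.05, 2266 genes passed in MUT and 5229 in CON. The count of 54 was 26 without MUT CT7 replicate 1, 27 without MUT CT19 replicate 2, 29 without MUT CT19 replicate 1 and 33 without MUT CT7 replicate 3. It was 107 without MUT CT13 replicate 2, 131 without CON CT13 replicate 3, 141 without MUT CT13 replicate 1, 19 with the mesothelium score as a covariate and 555 with array weights. Leaving out the 3 arrays of narrow spread, or 8 other sets of as many arrays of these groups, keeps 1 CON CT7 array. Over these omissions the MUT count went only with the CON CT13 array left out, and was lowest without replicate 1.

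The clock genes ran earlier in MUT. All 12 clock-list genes called in both genotypes peaked earlier, with shifts from -2.36 h (Clock) to -5.71 h (Per1), and all 12 had smaller fitted sizes, from 54.6% (Dbp) to 92.4% (Tef) of the size in CON, with a median of 71.9%. A choice of genes that passed in MUT favours kept sizes, and the 5 called in CON alone kept 18.1% (Tspan4), 27.8% (Ciart), 46.5% (Bhlhe40), 64.6% (Hlf) and 72.1% (Cry1). Nr1d1 moved from CT4.65 ± 0.19 to CT23.3 ± 0.34 (SE in hours), and Arntl from CT20.5 ± 0.35 to CT15.9 ± 0.39. The common shift of all 20 clock-list genes was -4.69 h, and it ranged from -4.99 to -4.49 when any array was left out. An exact permutation test of the genotype labels within time points, two-sided and chosen after the data were seen, gave p = 1.25e-05, the smallest that its 160000 assignments can give. The rhythm of these 20 genes, as the sum of squared amplitudes, was 2.32-fold stronger in CON (log2 ratio 1.21, exact permutation p = 0.0181, two-sided). Of the 54 and 2650 rhythmic genes, 33 were called in both genotypes, against 9.22 for independent lists. Of these, 31 peaked earlier in MUT, with a median shift of -4.25 h, and 21 had smaller sizes. Among those not in the clock lists, chosen after their values were seen, Phlda3 peaked at CT16.6 in CON and CT8.8 in MUT, and Slc7a8 at CT22.1 and CT19.8.

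Clock time was also estimated for each array, by fitting the 20 clock genes of that array to the CON rhythms after centring on the mean of its genotype, with each CON array left out of its own template. The 12 CON arrays deviated from the labelled time by -0.02 h on average (SD 0.996 h, from -1.63 to 1.63 h). All 12 MUT arrays were ahead, by 5 h on average (SD 1.52 h, from 2.17 to 7.45 h). The fitted strength was 1.01 ± 0.20 (SD, n = 12) in CON and 0.70 ± 0.22 in MUT. The mean resultant length of the deviations, a measure of agreement between mice that is 1 when all are equal, was 0.969 in CON and 0.929 in MUT. This difference of 0.04 did not pass (p = 0.745, permutation test with 100000 draws, two-sided). The permuted groups mix both genotypes, although MUT arrays were ahead by 5 h on average, so that shift widens the permuted differences. This p therefore does not decide on agreement between mice. The spread of the clock genes between mice of a group was 1.13-fold wider in variance in MUT (log2 0.18, p = 0.561, permutation test, two-sided), and 12 of the 20 genes had the wider spread there. It was narrower in MUT without MUT CT19 replicate 3 (log2 -0.28, permutation p = 0.302). The test of spread leaves open a difference in order between mice of a size that 12 arrays cannot resolve, and the test of agreement cannot decide it.

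**Figure D2:**
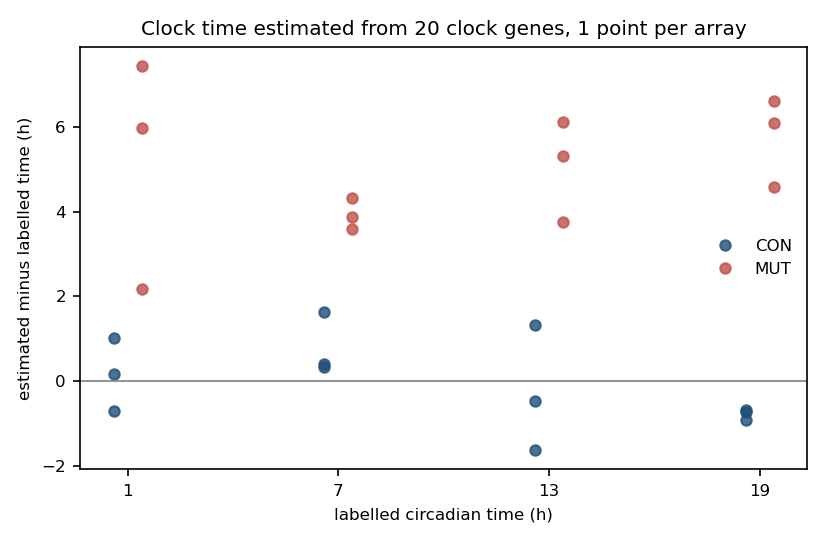
Estimated minus labelled circadian time in hours against the labelled time, 1 point per array, with CON in blue and MUT in red, set slightly apart for reading. CON arrays lie between -1.63 and 1.63 h and MUT arrays between 2.17 and 7.45 h.

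The difference of the rhythms itself passed in 223 genes, 15 of them from the clock lists. The largest vector differences were those of Nr1d1 (3.66 ± 0.24), Angptl8 (3.00 ± 0.47), Pisd-ps3 (2.32 ± 0.48), Pnpla3 (2.14 ± 0.27), Nr1d2 (2.03 ± 0.27) and Dbp (2 ± 0.24). Asb12 (1.83 ± 0.30), Bhlhe40 (1.83 ± 0.31), Ppp1r3c (1.82 ± 0.26), Npas2 (1.81 ± 0.24), Rbp7 (1.77 ± 0.27) and Mid1ip1, a regulator of fatty acid synthesis (1.71 ± 0.26), followed. Of the 223 genes, 204 had the smaller fitted size in MUT. A total of 186 genes were called rhythmic in CON, differed between genotypes and were not called in MUT. Their median size was 0.57 in CON and 0.26 in MUT, an order that the choice of these genes largely fixes. Lep fell from 1.38 to a fitted 0.19, Asb12 from 2.02 to 0.38, Pfkfb3 from 0.89 to 0.16, Ciart from 1.07 to 0.30 and Tspan4 from 0.81 to 0.15. Among the genes called in both genotypes, Angptl4 peaked at CT3.53 in CON and CT19.8 in MUT (vector difference 1.39 ± 0.19) and Nampt at CT15.8 and CT8.12 (0.97 ± 0.15). Gene calls that ended without single arrays were those of Clock (20 of the 24 arrays), Ppp1r3b (14), Gpihbp1 (12), Pisd-ps3 (9), Pck1 (6) and Sqle (2). Pdk4 differed by 1.27 ± 0.20, with a fitted size of 0.37 in CON (adjusted p = 0.133) and 1.03 in MUT.

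**Figure D3:**
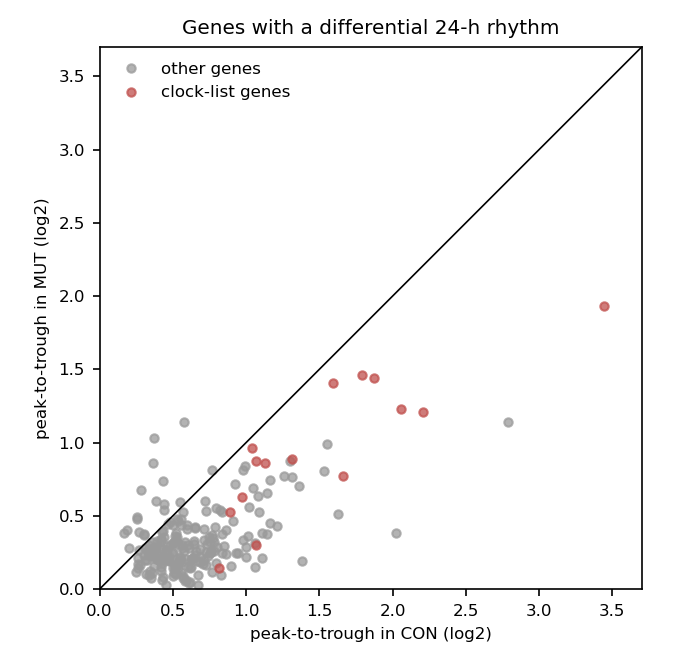
Fitted log2 peak-to-trough in MUT against that in CON for the 223 genes with a differential rhythm, with clock-list genes in red and the line of equal sizes in black. The points of 204 genes lie below the line.

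By list, 6 of 7 clock outputs (adjusted p = 1.82e-09, Fisher's exact test, one-sided), 6 of 9 repressors (adjusted p = 1.06e-08) and 3 of 4 activators (adjusted p = 9.26e-05) had a differential rhythm. The counts adjusted over the list alone were 6, 7 and 3. Of insulin signalling and glucose use 5 of 14 passed (7 adjusted over the list alone, adjusted p = 1.12e-05), namely Ppp1r3c, Ppp1r3b (1.66 ± 0.35), Pck1, the gene of a gluconeogenic and glyceroneogenic enzyme (1.54 ± 0.31), Pfkfb3 (0.95 ± 0.14) and Irs2 (1.11, adjusted p = 0.0425), the last chosen after its values were seen. Of the adipokines 2 of 8 passed (4 adjusted over the list alone, adjusted p = 0.0348), namely Lep (1.51 ± 0.20) and Nampt. Of the glucocorticoid targets 2 of 12 passed (7 adjusted over the list alone, adjusted p = 0.0658), namely Tsc22d3 (1.09 ± 0.11) and Pdk4. Of cholesterol synthesis 1 of 12 passed, Sqle (1.04 ± 0.20), against 10 adjusted over the list alone (adjusted p = 0.549). Of lipolysis and fatty acid handling 2 of 13 passed (5 adjusted over the list alone, adjusted p = 0.066), Angptl4 and Gpihbp1 (0.58 ± 0.12). The count of 223 was 119 without MUT CT19 replicate 1, 123 without MUT CT7 replicate 1, 124 without MUT CT7 replicate 3, 131 without CON CT19 replicate 2 and 135 without CON CT7 replicate 3. It was 148 without CON CT7 replicate 1 or MUT CT19 replicate 2, 371 without MUT CT13 replicate 2, 346 after quantile normalization, 438 with the mesothelium score as a covariate and 737 with array weights. Without the 3 arrays of narrow spread it was 175, 106 of them among the 223, and 8 other omissions of as many arrays gave 23 to 271, with a median of 63.

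Over all 15526 genes, the sum of squared 24-h amplitudes was 1.85-fold larger in CON (log2 ratio 0.89), which did not pass (p = 0.0585, exact permutation test over 160000 assignments, two-sided). It passed after quantile normalization (log2 ratio 0.97, exact permutation p = 0.0312) and with genes above the 60th percentile of signal (0.99, exact permutation p = 0.0483). It also passed without CON CT1 replicate 1 (0.93), CON CT1 replicate 2 (0.99), CON CT7 replicate 2 (0.94), CON CT13 replicate 2 (1.03) or CON CT13 replicate 3 (0.93). The same held without CON CT19 replicate 3 (0.98), MUT CT19 replicate 1 (0.92) or MUT CT19 replicate 2 (0.96), while without MUT CT19 replicate 3 the log2 ratio was 0.58. The same ratio and a common shift were computed for 17 gene lists, a test chosen after the data were seen. Heat shock genes had a 4.42-fold and cholesterol synthesis genes a 5.39-fold larger sum in CON, with exact permutation p of 0.00459 and 0.00936 and an adjusted p of 0.053 for both. The common shift passed for adipokines (-6.56 h, adjusted p = 0.000354), glucocorticoid targets (-4.03 h, 0.00287), lipolysis and fatty acid handling (-7.75 h, 0.0098) and insulin signalling (-7.03 h, 0.00984). In this order, the lists kept 25%, 37.8%, 44.1% and 45% of their CON strength at these shifts. The test exchanges the genotype labels, so a list that loses its rhythm in MUT and retains an arbitrary phase can also pass. A pass therefore does not tell a kept and shifted rhythm from a lost one. For cholesterol synthesis the shift was -9.21 h (adjusted p = 0.0098), with 10.2% of the CON strength kept. It was 6.61 h without MUT CT1 replicate 2, 10.1 h without MUT CT13 replicate 3 and -5.41 h without MUT CT19 replicate 1, and shifts near 12 h do not tell earlier from later. For extracellular matrix genes the shift was 0.13 h (exact permutation p = 0.944) and for heat shock genes -0.78 h (exact permutation p = 0.66).

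At each time point, MUT was compared with CON, 3 arrays against 3, with limma's two-sided moderated test. At CT1, 7 genes differed, 5 higher and 2 lower in MUT. Bhlhe40, a clock repressor gene, rose by 1.16 ± 0.22 (2.24-fold), Lep by 0.74 ± 0.14, Cmklr1, which encodes a receptor of the adipokine chemerin, by 0.67 ± 0.11, Mir339 by 0.56 ± 0.10 and Tsc22d3 by 0.53 ± 0.08. Supt4b fell by 0.75 ± 0.12 and Olfr92 by 0.72 ± 0.13. The arrays of the genotypes did not overlap in 7 of these 7 genes, which the choice of genes on the same arrays largely fixes (chance gives 10% for genes not chosen). Against all other genes, the clock outputs were higher as a list at CT1 with 0 of 7 members past the threshold and 5 adjusted over the list alone (camera, adjusted p = 2.15e-06, and adjusted p = 0.00621 with an estimated correlation). Clock repressors (adjusted p = 8.23e-05, and 0.0517 with an estimated correlation) and the unfolded protein response (2.34e-06, and 0.0836) were also higher, with 1 of 9 and 0 of 13 members past the threshold. So were heat shock genes (0 of 11, 0.000473, and 0.179), extracellular matrix genes (0 of 13, 0.000882, and 0.472) and glucocorticoid targets (1 of 12, 0.00208, and 0.179), each p adjusted. T cell (0 of 3, 0.0283, and 0.261), brown adipocyte (0 of 6, 0.0446, and 0.472) and oxidative phosphorylation genes (0 of 16, 0.0446, and 0.713) were lower. Of these lists only the clock outputs passed with an estimated correlation.

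Of 15 arrays, any omission moved the CT1 count by over 1.5 times. The limma count was 0 without CON CT1 replicate 1, MUT CT1 replicate 1 or MUT CT1 replicate 3 (1720, 1563 and 1454 genes at an unadjusted p under 0.05), 1 without CON CT1 replicate 2 and 2 without CON CT1 replicate 3. It was 3 without CON CT7 replicate 1 or 3, MUT CT7 replicate 2 or MUT CT19 replicate 1. It was 4 without CON CT7 replicate 2, CON CT13 replicate 1, CON CT19 replicate 2, MUT CT7 replicate 1 or MUT CT7 replicate 3, and 18 without CON CT13 replicate 3. Bhlhe40, Lep and Olfr92 (adjusted p = 0.0487 each) lost their call without 16, 17 and 18 of the 24 arrays, Mir339 without 12, Cmklr1 and Supt4b without 5 each and Tsc22d3 without 3. After quantile normalization 11 genes differed, 54.5% of them higher in MUT against 71.4% before.

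At CT7, 629 genes differed, 462 higher and 167 lower in MUT. Asb12 rose by 1.68 ± 0.21 (3.21-fold), Pnpla3 by 1.23 ± 0.19, the tubulin genes Tuba1b and Tuba1a by 1.21 ± 0.24 and 0.98 ± 0.22, Fam20c by 1.18 ± 0.27 and Pcbd1 by 1.09 ± 0.23. Lep rose by 1.04 ± 0.14, Adamts5 by 0.98 ± 0.19 and Nampt by 0.53 ± 0.11. Nr1d1 fell by 1.40 ± 0.17 (2.65-fold), Pisd-ps3 by 1.46 ± 0.34, Ciart by 0.91 ± 0.07, Pfkfb3 by 0.91 ± 0.10 and Dbp by 0.83 ± 0.17. Slc5a6, a vitamin transporter gene, fell by 0.92 ± 0.12, Slc43a1, an amino acid transporter gene, by 0.87 ± 0.13, Rbp7 by 0.91 ± 0.19 and Rasd1 by 0.84 ± 0.20. Of the clock genes, Clock (0.45 ± 0.09), Wee1 (0.55 ± 0.13) and Nfil3 (0.40 ± 0.10) rose. The clock repressors were lower as a list, with 2 of 9 members past the threshold and 4 adjusted over the list alone (camera, adjusted p = 1.51e-05, and adjusted p = 0.0411 with an estimated correlation). Smooth muscle and pericyte markers were higher, with Acta2 (0.51 ± 0.13), Notch3 (0.28 ± 0.07) and Des (0.31 ± 0.09) past the threshold among 7, and 5 adjusted over the list alone (adjusted p = 0.000519, and adjusted p = 0.43 with an estimated correlation). Mesothelium markers were higher with 0 of 8 past the threshold (adjusted p = 0.0408, and adjusted p = 0.639 with an estimated correlation). Lox, of the extracellular matrix list, rose by 0.58 ± 0.10. The calls of Acta2 (6 arrays), Notch3, Des and Nfil3 (5 each), Pisd-ps3 (4), Rasd1 and Wee1 (3 each), Fam20c (2), Tuba1a (1) and Rbp7 (1) ended without single arrays.

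The mesothelium score at CT7 was -0.65 ± 0.04 (SD, n = 3) in CON and -0.19 ± 0.36 in MUT. With it as a covariate 322 genes differed, 265 of them among the 629. The arrays of the genotypes did not overlap in 621 of the 629 genes, which the choice of genes on the same arrays largely fixes (10% by chance for genes not chosen). The count was 191 without CON CT7 replicate 3, 227 without MUT CT7 replicate 3, 241 without MUT CT7 replicate 2, 273 without CON CT7 replicate 2 and 2727 with array weights. Without the 3 arrays of narrow spread it was 49, of which 18 were higher and 31 lower, and 8 other omissions of as many arrays gave 14 to 90. The share of called genes that was higher in MUT was 73.4%, against 89.8% with the arrays shifted to the same median and 55.7% with the trend on signal level removed from each array.

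At CT13, 50 genes differed, 36 higher and 14 lower in MUT. Arntl rose by 1.16 ± 0.15 (2.23-fold), Npas2 by 1.09 ± 0.17, Cdkn1a by 0.94 ± 0.16 and Clock by 0.47 ± 0.09. Dtx4 rose by 0.76 ± 0.13, Klb, which encodes the coreceptor beta-klotho, by 0.71 ± 0.13, Hmgcs1 by 0.71 ± 0.14, Pfkfb3 by 0.70 ± 0.10 and Plekhg1 by 0.67 ± 0.14. Dbp fell by 0.91 ± 0.17, Per3 by 0.87 ± 0.16, Nr1d2 by 0.87 ± 0.19, Tef by 0.60 ± 0.11, Usp2 by 0.56 ± 0.10 and Tspan4 by 0.51 ± 0.10. Tsc22d3 fell by 0.41 ± 0.08 and Optc by 0.38 ± 0.08. The calls of Nr1d2 (15 arrays), Optc (10), Plekhg1 (4), Hmgcs1 and Tsc22d3 (3 each) ended without single arrays, and of the other named genes Arntl, Cdkn1a and Pfkfb3 passed in every omission and the rest ended in 1 or 2. As lists, clock outputs were lower with 4 of 7 members past the threshold and 7 adjusted over the list alone (camera, adjusted p = 1.59e-05, and adjusted p = 0.0122 with an estimated correlation). Clock activators were higher with 3 of 4 (3 adjusted over the list alone, adjusted p = 7.78e-05, and adjusted p = 0.0932 with an estimated correlation). Cholesterol synthesis genes were higher with 1 of 12 past the threshold and 6 adjusted over the list alone (adjusted p = 0.000222, and adjusted p = 0.656 with an estimated correlation). Extracellular matrix genes were higher with 0 of 13 and 4 adjusted over the list alone (adjusted p = 0.000367, and 0.656 with an estimated correlation), and epididymis markers were lower with 0 of 5 (adjusted p = 0.0291, and 0.131 with an estimated correlation).

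The arrays of the genotypes did not overlap in 50 of the 50 genes at CT13, which the choice of genes on the same arrays largely fixes (10% by chance for genes not chosen). The count was 4 without CON CT13 replicate 1, an array of narrow spread, 8 without MUT CT13 replicate 3, 29 without CON CT19 replicate 1, 30 without MUT CT19 replicate 1 and 33 without CON CT1 replicate 3. It was 89 without MUT CT13 replicate 1 and 196 without CON CT13 replicate 3. Without the 3 arrays of narrow spread limma called 0 genes, with 1367 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0522, and 8 other omissions of as many arrays gave 0 to 187. Over all of these omissions the CT13 count went only with the CON CT13 array left out, and its lowest value came only without replicate 1. In a fit of the 6 arrays of CT13 alone 1 gene passed, and with array weights 13 did. Of the 17 named genes 8 kept their call with array weights, and Clock, Dbp, Klb, Nr1d2, Optc, Per3, Plekhg1, Tef and Tsc22d3 did not. The share of called genes that was higher was 72%, against 93.2% (220 and 16 genes) with the arrays shifted to the same median and 58.3% with the level trend removed.

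At CT19, 425 genes differed, 299 higher and 126 lower in MUT. Angptl8 fell by 2.56 ± 0.33 (5.9-fold), Bhlhe40 by 1.77 ± 0.22, Ppp1r3c by 1.5 ± 0.18, Aacs by 1.29 ± 0.20, Sult1e1 by 1.23 ± 0.34, Ppp1r3b by 1.22 ± 0.25, Mid1ip1 by 1.13 ± 0.18 and Bhlhe41 by 1.07 ± 0.24. Mir328 rose by 2.51 ± 0.66, Nr1d1 by 2.24 ± 0.17 (4.73-fold), Cma2, which encodes a mast cell protease, by 1.85 ± 0.47, Zim1 by 1.80 ± 0.25, Nr1d2 by 1.16 ± 0.19 and Pck1 by 1.10 ± 0.22. Gbp4 and Trim12c each rose by 1.07 ± 0.25. Of the clock genes Cry1 fell by 0.62 ± 0.09, Usp2 by 0.60 ± 0.10 and Nfil3 by 0.45 ± 0.10.

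Fatty acid and triglyceride synthesis genes were lower as a list at CT19, with 5 of 17 members past the threshold, all lower, and 14 adjusted over the list alone (camera, adjusted p = 4.04e-10, and adjusted p = 0.447 with an estimated correlation). The transcription factor genes Srebf1 and Mlxipl fell by 0.85 ± 0.16 and 0.66 ± 0.14, Acacb by 0.61 ± 0.13 and Lpin1 by 0.44 ± 0.09, and 15 of 17 members had negative differences. Cholesterol synthesis genes were lower with 3 of 12 past the threshold and 9 adjusted over the list alone (adjusted p = 9.81e-08, and adjusted p = 0.447 with an estimated correlation). Insig1 fell by 1.04 ± 0.22, Cyp51 by 0.88 ± 0.20 and Sqle by 0.56 ± 0.14, and all 12 members had negative differences. The lipolysis and fatty acid handling list was higher, with 3 members higher, 1 lower and 5 of 13 past the threshold adjusted over the list alone (adjusted p = 0.0247, and adjusted p = 0.447 with an estimated correlation). Angptl4 rose by 0.93 ± 0.13, the glycerol channel gene Aqp7 by 0.40 ± 0.09 and Gpihbp1 by 0.36 ± 0.09, and G0s2 fell by 0.86 ± 0.17. Angptl4 and G0s2 encode inhibitors of lipases. Pdk4 rose by 1.04 ± 0.14, Hk2, which encodes a hexokinase, fell by 0.78 ± 0.13, and Nrg4 and Nampt fell by 0.37 ± 0.09 and 0.41 ± 0.11. Endothelium markers were higher with 0 of 8 past the threshold and 5 adjusted over the list alone (adjusted p = 0.0105, and adjusted p = 0.447 with an estimated correlation). Oxidative phosphorylation genes were lower with 1 of 16, Cox5b (fell by 0.54 ± 0.09), past the threshold (adjusted p = 0.0192, and 0.485 with an estimated correlation).

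**Figure D4:**
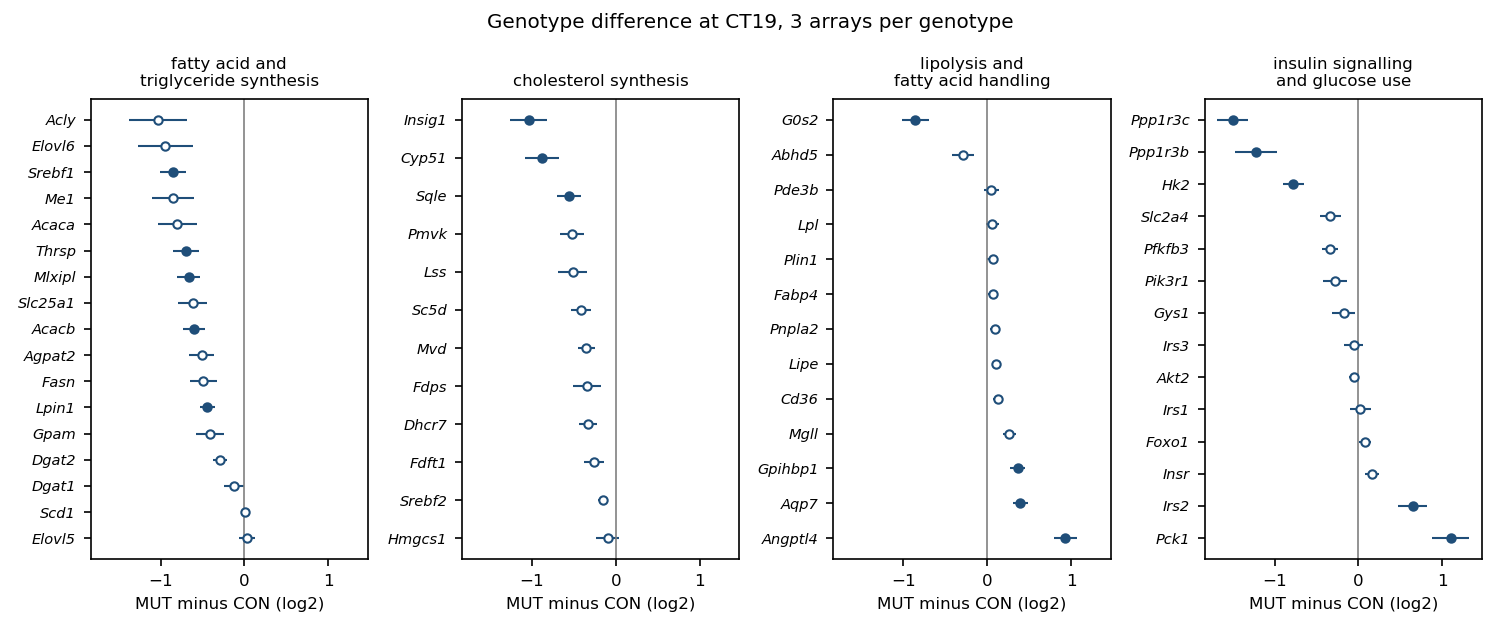
Log2 difference MUT minus CON at CT19 for the measured members of 4 fixed gene lists, with SE bars of the limma model (3 arrays per genotype). Filled points are below an adjusted p of 0.05 over all genes. All 12 cholesterol synthesis members and 15 of 17 fatty acid and triglyceride synthesis members lie below 0.

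The arrays of the genotypes did not overlap in 423 of the 425 genes at CT19, which the choice of genes on the same arrays largely fixes (10% by chance for genes not chosen). The calls of Sult1e1 and Nampt ended without any 1 of 12 arrays, that of Mir328 without any 1 of 7 and those of Bhlhe41, Nrg4 and Cma2 without any 1 of 5. Those of Gpihbp1, Nfil3, Sqle, Insig1, Cyp51, Mlxipl, Acacb, Aqp7, Pck1, Ppp1r3b, Gbp4, Trim12c, Lpin1, G0s2 and Srebf1 ended in 1 to 4 omissions. The count was 36 without CON CT19 replicate 2, 50 without MUT CT19 replicate 1, 61 without MUT CT19 replicate 2, 187 in a fit of the 6 arrays of CT19 alone, 662 with the arrays shifted to the same median and 1642 with array weights. The adipocyte markers had a median difference of 0.07 at CT19. The share of called genes that was higher was 70.4%, against 85% with the arrays shifted to the same median and 57.4% with the level trend removed.

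The daily mean, over the 4 time points, differed in 3365 genes, 1902 higher and 1463 lower in MUT. The majority was lower without a level filter (1862 higher, 2140 lower) and with all probe sets (2184 higher, 2507 lower). The median size among them was 0.15 (1.11-fold), and 12 genes reached 1.5-fold. Mir328 (1.40 ± 0.33), Gm6625 (1.27 ± 0.23), Folh1, which encodes a glutamate carboxypeptidase (1.11 ± 0.15), Cma2 (0.98 ± 0.23), Olfr1299 (0.88 ± 0.25), Pcbd1 (0.74 ± 0.11), Trim12c (0.74 ± 0.12) and Prr32 (0.66 ± 0.14) were the 8 highest. Rps4l-ps fell by 0.71 ± 0.16, Chchd10 by 0.56 ± 0.10, Man2a2 by 0.55 ± 0.10, Pisd-ps3 by 0.54 ± 0.17, Serpina3b by 0.50 ± 0.16, Mir122 by 0.49 ± 0.14, Angpt1 by 0.46 ± 0.15 and Mir1981 by 0.46 ± 0.10. Among the clock genes Clock rose by 0.27 ± 0.04, and Ciart, Usp2 and Cry1 fell by 0.21 ± 0.04, 0.20 ± 0.05 and 0.19 ± 0.05. Lep rose by 0.37 ± 0.07, Cdkn1a by 0.38 ± 0.08 and Hmgcs1 by 0.33 ± 0.07. Extracellular matrix genes were higher as a list, with 5 of 13 past the threshold and 6 adjusted over the list alone (camera, adjusted p = 0.000564, and adjusted p = 0.619 with an estimated correlation). Lox rose by 0.40 ± 0.05, Col6a1 by 0.30 ± 0.07, Fn1 by 0.29 ± 0.08 and Col5a1 by 0.17 ± 0.04. Fatty acid and triglyceride synthesis genes were lower with 2 of 17, Acacb (fell by 0.32 ± 0.07) and Slc25a1 (fell by 0.25 ± 0.09), and 1 adjusted over the list alone (adjusted p = 0.00812, and adjusted p = 0.619 with an estimated correlation). The calls of Slc25a1 (14 arrays), Serpina3b (11), Angpt1 (9) and Pisd-ps3 (3) ended without single arrays.

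Of the mesothelium markers 3 of 8 were higher in the daily mean (5 adjusted over the list alone), Lrrn4 (0.51 ± 0.16), Muc16 (0.49 ± 0.16) and Msln (0.44 ± 0.16), and the list did not pass (camera, adjusted p = 0.0581, and adjusted p = 0.619 with an estimated correlation). The calls of Msln and Muc16 ended without any 1 of 17 and 9 arrays, and the mesothelium score was higher in MUT by 0.26. With the score as a covariate 711 genes differed, 684 of them among the 3365. The direction went with the signal level: of 10 equal bins, the dimmest held 35 genes higher and 260 lower and the brightest 368 higher and 48 lower. The share of called genes that was higher was 56.5%, against 87.7% (3812 and 537 genes) with the arrays shifted to the same median. With the level trend removed 1858 genes differed, 1477 of them among the 3365, and after quantile normalization 1952. The count was 2146 without CON CT13 replicate 1, an array of narrow spread. It was 296 without the 3 arrays of narrow spread, below the 719 to 3886 of 8 other omissions of as many arrays.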

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

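The tests of the trend on signal level, of weak or mixed samples at CT19, of the synthesis list's rhythm in CON and at the clock's shift, and of DNA near Arntl were chosen only after the result was seen. A difference between groups was found in 223 genes, whose genotype difference changed between time points by limma's interaction test on the 24-h rhythm. The 12 largest were Nr1d1 (3.66), Angptl8 (3), Pisd-ps3 (2.32), Pnpla3 (2.14), Nr1d2 (2.03), Dbp (2), Asb12 (1.83), Bhlhe40 (1.83), Ppp1r3c (1.82), Npas2 (1.81), Rbp7 (1.77) and Mid1ip1 (1.71), as log2 vector differences. A signal in data outside the comparisons came from 5090 probe sets past the level filter without a single gene symbol. Of these 323 were rhythmic in CON and 1 in MUT, with 1276 and 652 at an unadjusted p under 0.05, while 19 had a differential rhythm and 844 differed in the daily mean.

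Chance was weighed by regrouping the arrays. Of 100 splits of the genotype labels within time points, 1, the real one, gave as many genes with a different daily mean (3365, highest other 1842), and 1 gave as many with a differential rhythm (223, highest other 59), so chance is excluded at a share of 0.05. Of 100 assignments of the CON arrays to time points, 1 gave as many rhythmic genes (2650, highest other 900). For MUT 4 of 100 did (54, highest other 154), and a count several times the real count points to a structure of the samples. What this structure is was not tested, and an assignment that retains part of the real times would also raise the count. The 10 splits of 6 arrays are too few for a share under 0.05. At CT1 1 split gave as many genes (7, highest other 0), at CT7 1 (629, highest other 0), at CT19 1 (425, highest other 0) and at CT13 2 (50, highest other 119, which points to a structure of the samples whose nature was not tested). Beside the limma counts of 0, the highest counts at an unadjusted p under 0.05 were 881 at CT1, 2216 at CT7 and 1893 at CT19.

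The many small differences of the daily mean (3365 genes, median size 0.15) went with signal level and with mesothelium markers. A trend with signal level as the whole cause is argued against by the 1858 genes called with the trend removed, 1477 of them among the 3365. A different share of mesothelial cells as the main cause was weighed by the share of the difference that the score predicts within groups. It was 0.14 in the median (0.114 to 0.1917 when any array was left out). Error in the score would lower this share, so a low value does not decide the question. The predicted and observed differences correlated across 3362 called genes (r = 0.634). Any pattern across arrays that follows the score within groups could give this, so r does not tell these cells from the level trend. With the score as a covariate 711 genes were called, but a lost call does not show a smaller difference. Both may contribute, and without the 3 arrays of narrow spread 296 genes were called. Whether and how genotype itself leads to these differences stays open and was not tested.

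The lower fatty acid and triglyceride synthesis genes at CT19 might be a rhythm that stayed intact and ran ahead with the clock genes. This is argued against by the share of its CON strength that the list kept at its best common shift, 17.6% (10.1 to 40.6% when any array was left out). That shift was -10.4 h, against -4.69 h for the clock genes, and when any array was left out it stayed around 12 h, from -7.63 h through 12 h to 8.22 h on the 24-h circle. The list had a rhythm in CON to keep (exact permutation p = 0.0236 over 369600 assignments, 1 of 17 members called), although p was 0.0581 to 0.0787 without CON CT1 replicate 2 or 3, CON CT7 replicate 2 or 3 or CON CT13 replicate 1. The spread within groups alone would give 29.9% of the CON strength. With that taken out, 25.1% was kept at the best shift (14.4 to 55.9%, the highest without MUT CT1 replicate 3) and 1.82% at the clock's shift (-17.3 to 22.4%). A weaker rhythm in MUT stays open. Weak or mixed samples that lower all adipocyte genes are argued against by the ratio of the median adipocyte marker difference to that of the list, -0.111 (-0.186 to -0.0166 without any 1 array of CT19). Adipocyte markers lie at the 99.6 percentile of signal, where a fall may be compressed, although Pck1 and Aqp7 rose on the same arrays. Whether and how genotype itself leads to the lower list at CT19 stays open and was not tested.

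Genes near Arntl had an excess of larger differences in the daily mean. Of the 200 nearest tested genes 12 (6%) passed with a difference of at least 0.25, against 287 of 15226 elsewhere (1.88%, odds ratio 3.32, Fisher's exact p = 0.00054, two-sided), and the odds ratio was 3.01 with the level trend removed. Of 66 windows of 200 neighbouring genes over the chromosomes, with the region near Arntl not taken out, 0 held as many such limma calls (median 3, highest 11). Trim12c (0.74), Rps4l-ps (-0.71) and Gde1 (-0.44, chosen after its values were seen) were among the 12. A candidate explanation is DNA linked to the targeted Arntl alleles, which differ between the genotypes, and the strain background is not given in the sources used here. Other ways in which genotype could act on these genes stay open and were not tested.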

How the results depend on the processing

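The level trend, mesothelium covariate and narrow-array alternatives were tests chosen only after the result was seen, as were the clock phase shift and the list tests after quantile normalization, with the level trend removed and without each array. The clock phase shift, the clock rhythm ratio, the phase coherence difference and the clock spread ratio kept direction and side of the threshold after quantile normalization, the median shift, level trend removal and removal of the letter means, and without the clock outputs. The phase shift and the rhythm ratio also did so with 3 arrays of narrow spread left out. The array weights, the mesothelium covariate, the level filters and the other treatments of probe sets were not run for these 4 results. The number of arrays and signal over background limit the counts. For the changes below the cause was not tested, except where fewer genes or arrays enter by construction or a fold minimum is added.

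Array weights gave 4194 genes for rhythm in CON, 555 in MUT, 737 for differential rhythm, 58 at CT1, 2727 at CT7, 13 at CT13 and 1642 at CT19. The mesothelium covariate gave 1470, 19 and 438 for the rhythms, 711 in the daily mean and 322 at CT7, and the fitted peak of Muc16 in CON moved by over 6 h at a size of 0.232. Muc16 is a member of the score's list, so the covariate takes out its rhythm by construction. With the narrow arrays out the counts were 1011 in CON, 296 in the daily mean, 49 at CT7 and 0 at CT13 (limma; 1367 at an unadjusted p under 0.05). Quantile normalization gave 346 for differential rhythm, 1952 in the daily mean, 11 at CT1 and a log2 total rhythm ratio (CON over MUT) of 0.968. The 60th percentile filter gave 2093 in the daily mean, 3 at CT1 and a log2 total rhythm ratio of 0.994. A fold of at least 1.5 left 431 in CON, 12 in the daily mean, 68 at CT7, 15 at CT13 and 72 at CT19. The median shift gave 236 at CT13 and 662 at CT19, and the level trend removed gave 1858 in the daily mean. All probe sets gave 22 at CT1 and 23 at CT13, no level filter 13 and 29, and the 6 arrays of a time point alone 30 at CT1, 1 at CT13 and 187 at CT19. Trended and robust variance gave 4 at CT1 and the replicate block 3. Without a level filter the majority of the daily mean turned to lower in MUT (1862 higher, 2140 lower), as it did with all probe sets (2184 higher, 2507 lower). With an estimated correlation 3 of 24 camera calls held, clock outputs at CT1 and CT13 and clock repressors at CT7. Fisher's test has no such setting and ignores correlation between members, so its 20 calls were not tested under this alternative. They are only carried along in the total of 23 of 44 list tests. After quantile normalization and with the level trend removed 38 of the 44 list calls held in each, and with the replicate block all 44. In both, the calls of extracellular matrix and of fibroblasts and preadipocytes for rhythm in CON, of brown adipocytes at CT1 and of epididymis at CT13 ended. After quantile normalization those of glucocorticoid targets in MUT and T cells at CT1 also ended, and with the level trend removed those of adipokines in CON and of lipolysis and fatty acid handling at CT19.

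When each array was left out, the ranges were 1843 to 2892 for rhythm in CON, 26 to 141 in MUT, 119 to 371 for differential rhythm, 2146 to 4131 in the daily mean, 0 to 18 at CT1, 191 to 732 at CT7, 4 to 196 at CT13 and 36 to 623 at CT19. As log2 values they were 0.575 to 1.03 for the total rhythm ratio, 1.03 to 1.36 for the clock rhythm ratio and -0.28 to 0.464 for the spread ratio. The ranges were 0.0166 to 0.0467 for coherence, -4.99 to -4.49 h for the phase shift, 41 to 54 list tests and 236 to 282 named genes. Of 289 named gene calls, 276 held with array weights, 264 with trended and robust variance, 254 after quantile normalization, 247 with the level trend removed and 193 with the mesothelium covariate. The losses were uneven: at CT13 8 of 17 held with array weights, and at CT1 3 of 7 held with the replicate block and 4 of 7 with trended and robust variance. With the covariate 22 of 59 held in the daily mean, 51 of 85 for rhythm in CON and 12 of 21 in MUT. At single time points 4 of 7 held with it at CT1, 22 of 32 at CT7, 17 of 17 at CT13 and 33 of 36 at CT19. For differential rhythm 32 of 32 held. The letters of the titles did not pair the arrays: the mean residual correlation was -0.0145 within a letter and 0.00719 between letters.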

Other observations

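Among glucocorticoid targets, Tsc22d3 had its CON peak at CT14 and differed from MUT at 3 of the 4 time points: it rose by 0.53 at CT1 and 0.30 at CT7 and fell by 0.41 at CT13, calls that ended without any 1 of 3, 5 and 3 arrays. Pfkfb3, a regulator of glycolysis, fell by 0.91 at CT7 and rose by 0.70 at CT13, and Nampt, which encodes an enzyme of NAD synthesis, rose by 0.53 at CT7 and fell by 0.41 at CT19, a call that ended without any 1 of 12 arrays. Cdkn1a rose by 0.94 at CT13 and by 0.38 in the daily mean. In the daily mean Ccl5, a chemokine gene, fell by 0.24, the brown fat markers Cidea and Ucp1 fell by 0.27 and 0.10, calls that ended without any 1 of 15 and 16 of the 24 arrays, and Tek, an endothelial receptor gene, rose by 0.24.

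Principal components 1 and 2 of the 24 arrays held 25.3% and 15% of the variance.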
